A study of Danio rerio with 11 samples.

How the data were processed

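Messenger RNA from 11 zebrafish tumours was measured on 1-colour Affymetrix arrays. Per the labels' protocols, the tumours were dissected, total RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. Per the labels, 6 arrays held malignant peripheral nerve sheath tumours (MPNSTs) from fish heterozygous for a mutation in a ribosomal protein (rp) gene, 3 held MPNSTs from fish homozygous for a p53 mutation, and 2 held seminomas. Of the rp arrays, 3 carried the label rpL35 (rp replicates 1 to 3) and 1 each carried rpL14 (replicate 4), rpS5 (replicate 5) and rpS11 (replicate 6). Replicate numbers within a group follow the order of the arrays in the series, and the labels pair no arrays across groups. The labels describe separate tumours and do not state that each came from its own fish, so the p-values measure the spread between these tumours.

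The deposited log2 values were GCRMA expression values, 1 per probe set and array. Per the submitters' processing notes, the authors made them with the affy and GCRMA tools, whose versions are not given in the sources used here. The log base was taken as 2 from the GCRMA method and the range of the values. The table held 15502 probe sets with 0 missing values and 0 Affymetrix control probe sets. Signal per array was alike, with medians from 5.55 to 6.01 log2 units and 9714 to 10154 probe sets above 4 log2 units. The number of arrays limits the precision of every comparison. Without detection calls, a value near the floor of the arrays cannot be told from absence, and a fold against such a value only roughly sizes a difference.

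Probe sets were named with the platform's annotation table, and symbols were updated through their Entrez identifiers against the RefSeq gene table of assembly GRCz12tu, which changed 1 symbol. Of the probe sets, 10795 had 1 gene symbol, 135 had several and 4572 had none. Probe sets entered the tests when their value was above 4 log2 units on at least 2 of the 11 arrays, which kept 11516 and left out 3986. They covered 7217 named genes, each represented for gene lists by the probe set with the highest mean over all arrays.

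Group means were fitted to the deposited log2 values in limma 3.58.1 under R 4.3.3, with all 11 arrays in 1 fit, moderated variances and a mean-variance trend. Limma's moderated two-sided test was adjusted by the Benjamini-Hochberg method over all tested probe sets of a comparison. A probe set counted as changed at an adjusted p under 0.05. The 5 comparisons were rp against p53 MPNST, MPNST (mean of both genotypes, weighted equally) against seminoma, rp MPNST against seminoma, p53 MPNST against seminoma, and the arrays labelled rpL35 against the other rp arrays. The last used a fit with 4 group means. Levels are given as mean ± SD and log2 changes as estimate ± SE.

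A fixed set of 29 gene lists was tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated per list. Limma's fry ran beside it, which asks whether the genes of a list move on balance one way and does not compare them with other genes. The lists named 1786 gene symbols, of which 1715 were resolved to current symbols. Several lists shared members, for example casp8 and baxa in both the p53 target and apoptosis lists, and h1m, buc and zar1 in both the germ cell and oocyte lists. The mutated genes were given per array with an exact two-sided permutation test where several arrays carried the mutation. Similarity of arrays was the mean Pearson correlation, across tested probe sets, of pairs within a genotype minus that of pairs between genotypes, with an exact one-sided permutation of the 9 MPNST labels.

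Named genes followed a rule. For each of the 2 main comparisons (rp against p53 MPNST, and MPNST against seminoma) it took the 10 genes with the largest rise and the 10 with the largest fall among changed probe sets with 1 symbol and no overlap between the groups. Each gene entered through its probe set with the highest mean over all arrays, so a gene changed only on a dimmer probe set was not eligible. Placeholder symbols were passed over. For the arrays labelled rpL35 against the other rp arrays it took 5 in each direction. It added the 4 members with the smallest p of every list in the 2 main comparisons, and mdm2, ccng1, tp53, cdkn1a, rpl35, rpl14, rps5 and rps11. No probe set was named tp53, cdkn1a, rps5 or rps11 in the annotation used, so these genes were not analysed here. Other genes named from the lists were chosen after their values were seen.

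The groups, comparisons, tests, filters, gene lists, naming rule and most alternatives were fixed before the data were examined. Alternatives chosen after seeing the data were a fit with each array's mean of the oocyte and ovary list as a covariate, a fit with the oocyte and liver list means as covariates, a fit with a block for 2 sets of arrays seen in the signal floor, and a comparison with seminoma within 1 of those sets. The alternatives fixed beforehand were no filter, a mean above 6 log2 units (7661 probe sets), quantile normalization, median centring, variances without a trend or with a robust trend, array weights, a minimum log2 change of 1, single arrays left out, and subsets of arrays.

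The tests were checked on simulated data with the real group sizes and the spread of the real probe sets. For rp against p53 MPNST, a planted log2 change of 1 was recovered for 9.23% of probe sets, a change of 2 for 54% and a change of 3 for 68.1%. For MPNST against seminoma the shares were 4.29%, 42.9% and 78.4%, and for the arrays labelled rpL35 against the other rp arrays 4.62%, 43.8% and 59.7%. The simulated MPNST and seminoma data gave 92 calls, 7 of them false, against 3388 in the real data. The Benjamini-Hochberg cut-off is less strict with more changes, so the shares may understate recovery there. A planted list shift was called and 0 of 28 unmoved lists were. The simulated genes varied independently of each other. This check therefore says nothing about lists whose genes move together, such as oocyte and ovary, with an estimated correlation of 0.951. Figures and tables were made with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.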

Results

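Gene expression was measured in 11 zebrafish tumours with 1 array per tumour. MPNSTs arise in the sheath of peripheral nerves, and seminomas are germ cell tumours of the testis. Per the labels, 6 arrays held MPNSTs from fish heterozygous for an inactivating mutation in a ribosomal protein gene, the rp group. Of these, 3 carried the label rpL35 and 1 each rpL14, rpS5 and rpS11, numbered replicates 1 to 6 in that order. Another 3 arrays held MPNSTs from fish homozygous for an inactivating p53 mutation, the p53 group. The last 2 held spontaneous seminomas from fish of mixed backgrounds, which served as tumours of another type. Array medians ranged from 5.55 to 6.01 log2 units, and 9714 to 10154 probe sets per array lay above 4 log2 units. The arrays fell into 2 sets by the median of 3125 dim probe sets, a measure of the signal floor. It was 2.51 to 2.68 log2 units on the arrays labelled rpL35 and the p53 arrays, and at most 2.36 on the rpL14, rpS5, rpS11 and seminoma arrays. Values within or blocked by these array sets stand beside the comparisons below.

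The mutated genes themselves were compared first, to see whether tumours of a mutant line carried less mRNA of the mutated gene. The mRNA of rpl35, a protein of the large ribosomal subunit, was at 14.08, 12.91 and 13.91 log2 units on the arrays labelled rpL35 (replicates 1, 2 and 3). The other 6 MPNST arrays were at 14.06 ± 0.05 (SD, n = 6). Replicate 2 was 2.21-fold below the median of those arrays, and replicates 1 and 3 lay close to it. The 73 other ribosomal protein genes were low on replicate 2 too, at -0.363 log2 units from their MPNST mean, which left rpl35 at -0.648 relative to them. The means differed by -0.43 log2 units, with an exact two-sided permutation p of 0.0595 over 84 splits, where 0.0119 is the smallest possible. Without replicate 2 the difference was -0.07 (exact p = 0.321). The exact p was 0.0238 after quantile normalization, 0.0357 without replicate 1, 0.179 without replicate 3 and 0.548 after median centring, where the difference was -0.255. Over all alternatives it ran from 0.0238 to 0.548. The mRNA of rpl14, another large subunit protein, was at 12.92 on the array labelled rpL14 (replicate 4) and at 13.84 ± 0.27 (SD, n = 8) on the other MPNST arrays. It was the lowest of the 9 MPNST arrays, 1.96-fold below the median of the others, and with 1 such array the difference was not tested. The seminomas had rpl35 at 14.42 and 14.36. Where the probes of rpl35 and rpl14 lie relative to the mutations is unknown, and tp53, rps5 and rps11 were not analysed here.

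**Figure D1:**
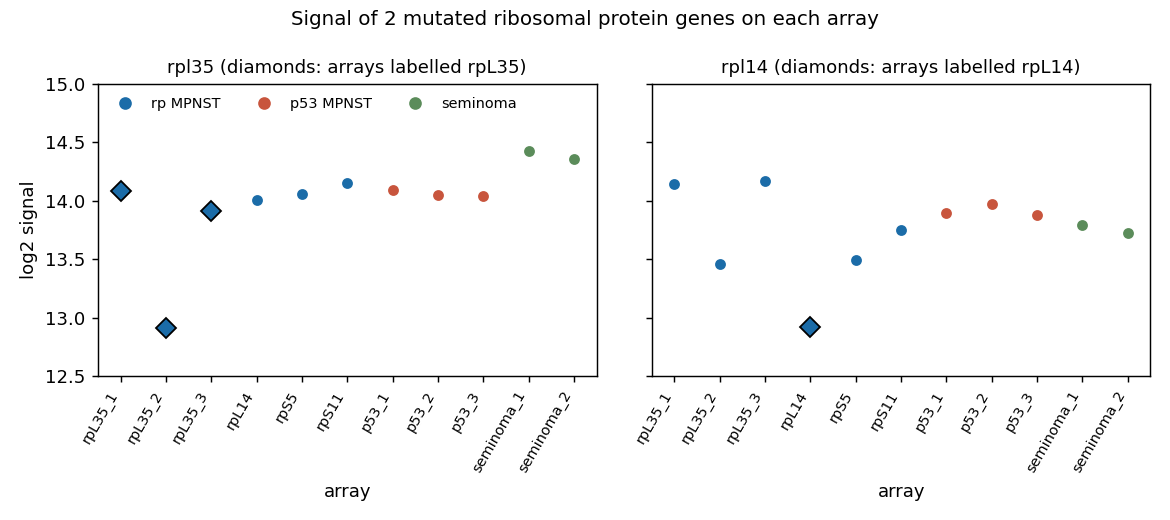
Log2 signal of rpl35 and rpl14 (vertical axis) on each of the 11 arrays (horizontal axis), with diamonds for arrays that carry the label of that gene. The rpL35 diamonds are at 14.08, 12.91 and 13.91 and the rpL14 diamond is at 12.92.

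Markers of other tissues differed widely among the MPNST arrays of both genotypes. Transcripts of oocytes and ovary, such as the egg coat gene zp3a.1 and the oocyte linker histone h1m, were near the floor on some arrays and abundant on others. On rp replicates 1 to 6 the mean of the 17 tested oocyte and ovary genes was 2.94, 11.87, 5.55, 11.48, 11.91 and 11.02 log2 units. On the p53 replicates it was 2.88, 11.05 and 8.86, and on the seminomas 5.27 and 4.96. The liver list, with fibrinogen and transferrin among its genes, averaged 12.12 in rp replicate 3 and 4.13 to 5.44 on the other arrays. The pancreas and gut list, with digestive enzymes such as prss1, averaged 10.82 in rp replicate 3 and 3.08 to 4.22 elsewhere.

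Whole arrays were compared to see whether tumours of 1 genotype resembled each other more than tumours of the other genotype. The mean correlation across probe sets was 0.791 within rp (range 0.651 to 0.948), 0.856 within p53 and 0.812 between the genotypes (range 0.694 to 0.917). The within minus between difference was -0.01, with a one-sided exact permutation p of 0.524 over 84 splits. Its sign turned without rp replicate 1, rp replicate 3 or p53 replicate 2, to 0.0232, 0.0228 and 0.00231. Rp replicate 1 and p53 replicate 1, both low in oocyte transcripts, correlated at 0.894. Rp replicate 1 was at 0.699 to 0.741 with the other rp arrays. The MPNST arrays with oocyte means of at least 11.02 correlated with each other at 0.909 to 0.948, p53 replicate 2 among them. Rp replicate 3, high in liver transcripts, was at 0.651 to 0.76 with every other MPNST array. Among such differences the test cannot exclude a resemblance by genotype. Rp replicate 2 and p53 replicate 2 shared 198 values equal in every digit given, 181 of them in probe sets too dim to be tested, while any other pair shared at most 7. Their median was 2.78 log2 units, and over tested probe sets the SD of the difference between these arrays was 1.1. The cause was not tested. MPNST arrays correlated with seminoma arrays at 0.581 (range 0.544 to 0.631), and the seminomas with each other at 0.978. Probe sets are not independent replicates, so these correlations only rank the pairs.

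The comparison of rp with p53 MPNSTs asks how tumours of the same type differ in mRNA between these genotypes. The genes with the largest rise in rp tumours were snu13a, a protein of the spliceosome and of small nucleolar RNA particles, and fah, the last enzyme of tyrosine breakdown. The mRNA of snu13a was at 7.11 ± 1.40 (SD, n = 6) in rp and 1.82 ± 0.29 (SD, n = 3) in p53 tumours, a change of 5.30 ± 0.75 (SE, adjusted p = 0.0162). The fah gene was at 7.51 ± 1.01 (SD, n = 6) against 3.19 ± 0.08 (SD, n = 3), a rise of 19.9-fold (adjusted p = 0.00959). Among named genes, taken by their brightest probe set, the largest falls were those of hoxc8a, a transcription factor of body axis position, by 4.89 ± 0.77 log2 units (adjusted p = 0.0292), and timp2b, an inhibitor of matrix metalloproteinases, by 3.73 ± 0.51 (adjusted p = 0.0125). The smallest adjusted p of a named gene was that of sost, a secreted inhibitor of Wnt signalling, at 2.19 ± 0.14 in rp and 4.43 ± 0.37 in p53 tumours (SD, n = 6 and 3, adjusted p = 0.000344).

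The other named rises were add1, an adducin of the membrane skeleton, by 3.64 ± 0.51 log2 units, rnf146, a ubiquitin ligase that recognises poly-ADP-ribosylated proteins, by 3.06 ± 0.32, and cmasa, which activates sialic acid, by 2.40 ± 0.38. Their adjusted p-values were 0.0151, 0.00289 and 0.0292. The other named falls were the nuclear lamin gene lmna (-2.40 ± 0.38), the caveolin gene cav2 (-2.29 ± 0.36), ptpdc1b (-2.21 ± 0.36), the body axis gene hoxb7a (-2.18 ± 0.38), uevld (-2.15 ± 0.35) and the calcium channel gene orai1b (-1.76 ± 0.29). Their adjusted p-values ran from 0.0292 to 0.0481. All of these 14 genes parted every rp array from every p53 array, as the naming rule required. Several sat near the floor in 1 of the groups, among them sost, fah and snu13a, so their folds are rough. A second probe set of snu13a was at -0.56 and one of hoxc8a at -1.21, and neither passed. Of the other rnf146 probe sets 1 passed at 3.65 and 1 did not at 1.29. On a dimmer probe set tfpia (-5.20), lin7c (-4.86), fundc2 (-3.92), rnf19a (-3.60) and pik3r3b (-3.00) also fell (adjusted p at most 0.0292). These genes were chosen after their values were seen, and their brightest probe sets did not pass. The other probe sets of lin7c were at -0.17 and 0.19, so its fall rests on 1 probe set. Those of tfpia, fundc2, rnf19a and pik3r3b had negative values. The gene rad23b also fell on 1 probe set (-2.34), with its other at 0.21. The fah gene is also a liver marker, yet rp replicate 3, the array with abundant liver transcripts, held it at 7.80 against up to 8.99 on another MPNST array.

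**Figure D2:**
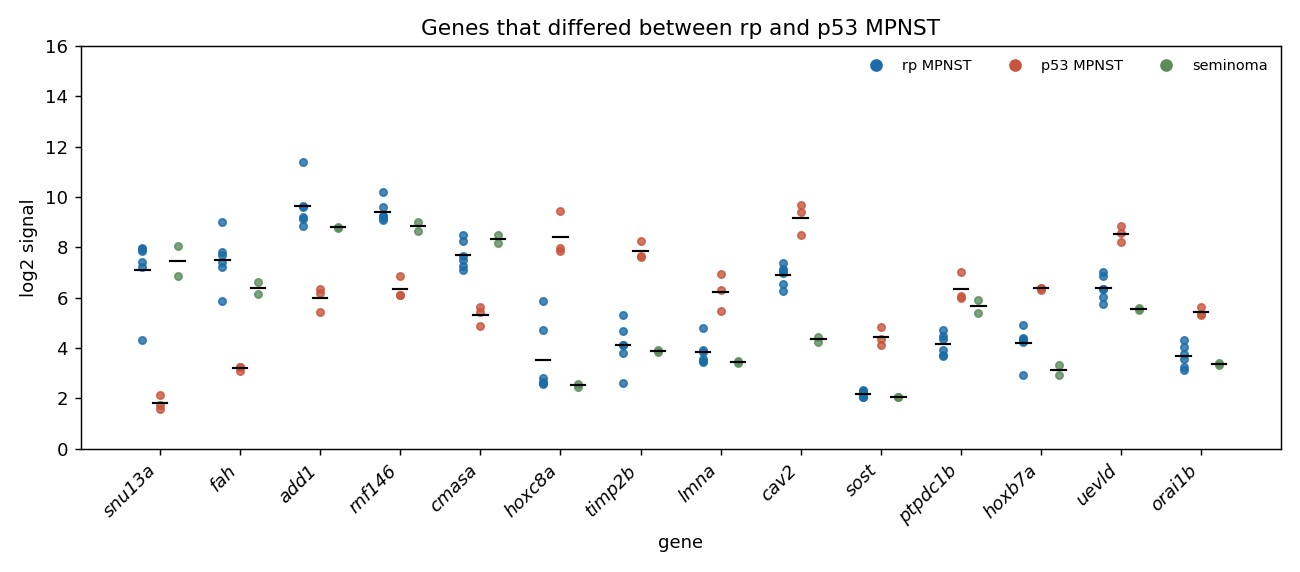
Log2 signal (vertical axis) of the 14 named genes that passed between rp and p53 MPNST, with points for arrays of the rp, p53 and seminoma groups and lines for group means. Every rp point lies apart from every p53 point, as the naming rule required, and sost sits at 2.19 in rp and 4.43 in p53 tumours on average.

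Across the arrays 39 probe sets passed, 13 higher and 26 lower in rp, and 1311 had an unadjusted p under 0.05. All 39 changed at least 2-fold and showed no overlap between the groups, which held for 5.32% of all tested probe sets against 2.38% by chance. The smallest adjusted p (5.9e-06) was that of a probe set without a gene symbol that fell by 6.66 log2 units and was chosen after its value was seen. Single arrays moved the count beyond 1.5 times. It was 93 without rp replicate 1, 72 without rp replicate 3, 24 without rp replicate 4, 24 without rp replicate 5, 22 without rp replicate 6, 17 without p53 replicate 1 and 10 without p53 replicate 3. It was 17 probe sets with the array sets as a block, 10 higher and 7 lower, of which 14 were among the 39. The other 25 kept a median share of 0.925 of their change with the block (lowest 0.821), at a median SE of 0.484 against 0.483, with unadjusted p-values of at most 0.00112. This blocked value equals that of the arrays labelled rpL35 alone against p53, since those are the rp arrays of the p53 arrays' set.

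The calls of single genes rested on few arrays. Of the 14 named genes, rnf146 and sost passed under every alternative in which they were tested (highest adjusted p 0.0194 and 0.0027), and all 14 kept their direction wherever tested. Dim genes such as sost are not tested with a mean above 6 log2 units. The calls of 11 of them ended without p53 replicate 1, 8 without p53 replicate 2, 12 without p53 replicate 3, 10 with the array sets as a block and 8 with the 9 MPNST arrays fitted alone. Without rp replicates 2, 4, 5 and 6 the calls of 5, 7, 8 and 7 genes ended. The changes themselves stayed of similar size. Without p53 replicate 3, for example, snu13a was at 5.17 (5.30 over all arrays), hoxc8a at -5.17 (-4.89) and lmna at -2.04 (-2.40).

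Of the 28 p53 target genes measured, 0 passed between the genotypes over all genes in limma and 5 had an unadjusted p under 0.05. Adjusted over the list alone 1 passed, casp8, an initiator of apoptosis, at -1.43 ± 0.32 log2 units. The p53 inhibitor mdm2, itself a p53 target, was at 6.84 ± 0.68 in rp and 6.58 ± 0.41 in p53 tumours (SD, n = 6 and 3, adjusted p = 0.845). With the array sets as a block its difference turned to -0.25 and stayed short of the threshold. The target ccng1, a cyclin, was at 12.27 ± 0.27 and 12.23 ± 0.22 (adjusted p = 0.958), a difference of 0.03 whose sign turned in several settings. The list's median change was -0.206 (adjusted p = 0.539). Limma's fry gave 0.0283 for a change of its genes on balance one way and 0.00633 for changes in either direction. Neither value was adjusted over the 29 lists. For a change on balance, fry gave smaller unadjusted values to the extracellular matrix (0.0102), endothelial (0.022) and immediate early and heat shock (0.022) lists. For changes in either direction it gave a smaller value to the extracellular matrix list (0.0022). Among the 9 p53 family members and regulators 0 passed and 0 had an unadjusted p under 0.05 (list adjusted p = 0.566), with mdm4 at 0.30 and chek1 at 1.18. The apoptosis and DNA repair list had 0 of 29 past the test and 3 at an unadjusted p under 0.05, casp8 again was lower adjusted over the list alone, and the list was not called (adjusted p = 0.934).

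As groups, 8 of the 29 lists shifted between rp and p53 tumours at camera's preset correlation, and 0 did with an estimated correlation, where 1 list had an unadjusted p under 0.05. Immediate early and heat shock genes were lower in rp tumours, with a median of -0.643 over 40 genes (adjusted p = 0.000693, and adjusted p = 0.76 with an estimated correlation). Of these, 0 passed over all genes in limma, 9 had an unadjusted p under 0.05, all lower, and 2 were lower adjusted over the list alone, the rapid response transcription factors egr1 (-3.25 ± 0.65) and ier2a (-2.62 ± 0.63). Leukocyte genes had a median of -0.674 over 42 genes (adjusted p = 0.000693, and adjusted p = 0.832 with an estimated correlation). Rp replicate 3, the array with abundant liver transcripts, went the other way at a list mean of 9.46 log2 units. The p53 arrays were at 8.40 to 9.30 and the other rp arrays at 7.54 to 8.35. Of the leukocyte genes, 0 passed over all genes and 8 had an unadjusted p under 0.05, with the neutrophil enzyme mpx at -4.30 ± 1.12 and the macrophage receptor marco at -1.69 ± 0.46. Adjusted over the list alone 1 was higher, polr1g (1.65 ± 0.36), a subunit of RNA polymerase I that entered the list through an older synonym. Endothelial genes had a median of -0.83 over 10 genes, 0 past the test and 2 at an unadjusted p under 0.05, with mrc1a at -1.60 (adjusted p = 0.00496, and adjusted p = 0.76 with an estimated correlation). Extracellular matrix genes had a median of -0.435 over 44 genes, of which timp2b fell, adjusted over the list alone too, and 7 had an unadjusted p under 0.05, with ccn2a at -1.89 and the proteoglycan gene dcn at -1.68 (adjusted p = 0.00682, and adjusted p = 0.76 with an estimated correlation).

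Proliferation genes leaned higher in rp tumours over all arrays, with 57 of 76 at positive values, a median of 0.502, 0 past the test and 5 at an unadjusted p under 0.05 (adjusted p = 0.0108, and adjusted p = 0.832 with an estimated correlation). The replication helicase genes mcm7 and mcm4 were at 0.85 and 1.31. The list's mean change of 0.413 turned to -0.212 with the array sets as a block (adjusted p = 0.958), a negative mean that came from rp replicate 3. All 17 oocyte and ovary genes were at positive values too, with a median of 1.48 (adjusted p = 0.0696). Both lists went together on most MPNST arrays. Those with oocyte means of 11.02 to 11.91 had proliferation means of 8.73 to 9.30. On p53 replicates 1 and 3, with oocyte means of 2.88 and 8.86, proliferation averaged 7.68 and 7.84. Rp replicate 1 was an exception, low in oocyte genes at 2.94 with a proliferation mean of 8.74. This was close to the 8.73 of p53 replicate 2 with oocyte genes at 11.05. With the oocyte list as a covariate the mean change of proliferation genes was 0.195 against 0.413. Rp replicate 3, the array with abundant liver transcripts, had the lowest proliferation mean at 6.14 log2 units against 7.68 to 9.30 on the other MPNST arrays, and rp replicate 2 of the same array set was at 8.73. Skeletal muscle genes had a median of 0.603 over 29 genes, 0 past the test and 1 at an unadjusted p under 0.05, with mybpc2b at 1.92 (adjusted p = 0.03, and adjusted p = 0.832 with an estimated correlation). Ribosomal proteins leaned lower in some rp tumours. Large subunit genes averaged 13.62 to 13.96 log2 units in rp replicates 2, 4, 5 and 6, and 14.16 and 14.23 in rp replicates 1 and 3, above the 14.05 to 14.10 of the p53 arrays. The large subunit list had 34 of 44 genes at negative values and a median of -0.138 (adjusted p = 0.03, and adjusted p = 0.832 with an estimated correlation). The small subunit list had a median of -0.145 over 30 genes (adjusted p = 0.0331, and adjusted p = 0.832 with an estimated correlation). The examples rplp2 (-0.61) and rps25 (-0.48) did not pass, and 0 genes of either list did, over the list alone too, while 1 and 3 had an unadjusted p under 0.05.

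Several of these list calls ended in other settings. With the array sets as a block the adjusted p was 0.298 for the large subunit, 0.192 for the small subunit, 0.958 for proliferation, 0.116 for skeletal muscle and 0.0602 for endothelial genes. The mean change stayed close for the small subunit (-0.115 against -0.124) and endothelial genes (-0.766 against -0.891). It shrank for the large subunit (-0.0759 against -0.135) and muscle (0.455 against 0.702). With the oocyte list as a covariate it was 0.345, 0.218 and 0.122 for the large subunit, small subunit and proliferation lists. Without p53 replicate 1 the calls of the large subunit (0.0537), small subunit (0.0537), proliferation (0.0923), matrix (0.0551), muscle (0.0537) and leukocyte (0.0537) lists ended, which left 2 lists. The mean change of proliferation genes then fell from 0.413 to 0.21 and that of leukocyte genes went from -0.58 to -0.349. Those of the large subunit, small subunit and muscle lists stayed close to their values over all arrays. Proliferation also ended without rp replicate 1 (0.148) and rp replicate 5 (0.0739, mean change 0.251). The large subunit list ended without rp replicate 2 (0.499, mean change -0.0697 against -0.135), rp replicate 5 (0.0881), p53 replicate 2 (0.0504) and p53 replicate 3 (0.0648). The small subunit list ended without rp replicate 2 (0.434, mean change -0.0577 against -0.124), rp replicate 5 (0.114) and p53 replicate 2 (0.117). The muscle list ended without rp replicates 1, 3 and 4 (0.052, 0.127 and 0.0543, with a mean change of 0.464 without replicate 4 against 0.702) and p53 replicate 2 (0.147). Over all alternatives the adjusted p ran from 6.5e-12 to 0.958 for proliferation, 0.00109 to 0.832 for the large and 0.00724 to 0.832 for the small subunit, and 0.00195 to 0.832 for muscle. It ran from 0.00109 to 0.76 for matrix, 3.54e-07 to 0.832 for leukocyte, 0.00102 to 0.76 for endothelial and 1.78e-05 to 0.76 for immediate early genes.

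The remaining lists were not called between rp and p53. Apart from fah, 0 of their genes passed in limma, and 0 to 7 per list had an unadjusted p under 0.05. Hypoxia and glycolysis had 5 of 40 at an unadjusted p under 0.05 (list adjusted p = 0.0645). The hypoxia marker ca9, at 2.40 ± 0.20 in rp and 7.02 ± 2.87 in p53 tumours (SD, n = 6 and 3), and the glycolysis regulator pfkfb3 (-2.74 ± 0.67) were lower adjusted over the list alone. Over all genes ca9 had an adjusted p of 0.0843, and 3.09e-05 without p53 replicate 1, within a range of 3.09e-05 to 0.27. The adjusted p was 0.0658 for oxidative phosphorylation, 0.0712 for pancreas and gut, 0.0734 for germ cell genes (median 0.778, moving with the oocyte list, whose genes h1m, buc and zar1 it shares) and 0.0953 for liver, where fah rose. It was 0.247 for mesenchymal and fibroblast genes, where adjusted over the list alone the smooth muscle actin gene acta2 (2.73) was higher and s100a10b (-1.70) lower. It was 0.312 for spermatid and sperm, 0.515 for Schwann cell and neural crest, 0.566 for kidney, 0.594 for both ribosome biogenesis and mitochondrial ribosomal proteins, and 0.602 for both erythroid and nervous system genes. It was 0.706 for epidermis and epithelium, 0.742 for both translation factors and Sertoli and Leydig cells, and 0.922 for growth factor signalling in nerve sheath tumours. Median, mean and test differed in sign for 3 lists. Ribosome biogenesis had a median of -0.0615, a mean of 0.0194 and a test leaning up, erythroid a median of -0.183, a mean of 0.0183 and a test leaning down, and growth factor signalling a median of -0.0869, a mean of -0.0823 and a test leaning up.

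The comparison of MPNST with seminoma asks what sets the nerve sheath tumours apart from a tumour of another tissue. Some genes of the neural crest and of Schwann cells, the glia of peripheral nerves, were high in MPNST. The transcription factor gene sox10, a master regulator of neural crest glia, was at 10.89 ± 1.80 in MPNST (SD, n = 9) and 3.02 ± 0.68 in seminoma (SD, n = 2), a change of 7.97 ± 1.26 (adjusted p = 0.000852). The glial calcium-binding protein gene s100b was at 12.42 ± 1.54 against 4.15 ± 0.04 (SD, n = 9 and 2), a change of 8.43 ± 1.03 (adjusted p = 0.000144). Seminomas held the transcripts of meiosis and of sperm tails. The meiotic chromosome axis gene hormad1 was at 2.42 ± 0.12 in MPNST and 13.70 ± 0.10 in seminoma (SD, n = 9 and 2), a fall of 11.27 ± 0.22 log2 units (adjusted p = 1.35e-10), and tekt1, of the sperm tail, fell by 10.08 ± 0.24.

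The other largest rises were defbl1, a defensin (10.64 ± 0.51), the water channel gene aqp1a.1 (9.35 ± 1.16), the homeobox gene dlx5a (8.94 ± 1.05), tuba8l3 (8.10 ± 1.27), pcbp4 (7.83 ± 0.99), the growth factor gene mdkb (7.24 ± 1.28), the keratin gene krt4 (7.04 ± 0.93) and fhl3b (6.97 ± 0.72). The other largest falls were the tubulin gene tuba7l (-9.96 ± 0.39), gsdf (-9.88 ± 0.36), a growth factor of gonadal somatic cells, nme5 (-9.70 ± 0.17), cimap1b (-9.65 ± 0.57), capsla (-9.58 ± 0.21), cimip2b (-9.54 ± 0.20), rsph9 (-9.48 ± 0.19), of the cilium's radial spokes, and cfap90 (-9.36 ± 0.18). In rp replicate 3, with its liver and pancreas transcripts, sox10 was at 6.39 and s100b at 8.53, the lowest of the rp arrays. The seminoma means of the risen genes and the MPNST means of the fallen ones mostly lay near the floor, so these folds are rough.

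Of the 29 lists 8 shifted between MPNST and seminoma at camera's preset correlation, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Of 38 spermatid and sperm genes 34 fell and 0 rose, with a median of -6.43, among them the ciliary genes spag6 (-8.99) and rsph14 (-7.18) (adjusted p = 1.42e-26, and adjusted p = 0.0552 with an estimated correlation). Adjusted over the list alone 34 fell and 1 rose. Of 32 germ cell genes 13 fell and 0 rose, over the list alone too, with a median of -2.9. They included the synaptonemal complex genes sycp3 (-9.31) and sycp1 (-8.14), the germ plasm helicase gene ddx4 (-7.68) and the piwi gene piwil1 (-6.94). The list had an adjusted p of 0.02, and adjusted p = 0.739 with an estimated correlation. It moved with the oocyte list, and germ cell genes averaged 8.63 in rp replicate 2 and 4.07 in rp replicate 1, whose oocyte means were 11.87 and 2.94. Of 16 Sertoli and Leydig cell genes, which mark the somatic cells of the testis, 8 fell and 1 rose (adjusted over the list alone 9 and 1). Among them amh (-7.48) and dmrt1 (-8.99) fell and the inhibin subunit gene inhbaa (3.33) rose (median -3.17, adjusted p = 0.0197, and adjusted p = 0.163 with an estimated correlation).

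Schwann cell and neural crest genes rose as a list, with 9 of 28 up and 3 down (adjusted over the list alone 9 and 4) and a median of 1.09 (adjusted p = 0.02, and adjusted p = 0.25 with an estimated correlation). Beside sox10 and s100b, crestin (6.64) and foxd3 (5.33) rose, and sox8b (-5.36), msx1b (-3.24) and the brain fatty acid binding protein gene fabp7a (-4.29) fell. Of 42 leukocyte genes 18 rose and 2 fell (adjusted over the list alone 24 and 2), with a median of 1.78 (adjusted p = 1.41e-05, and adjusted p = 0.491 with an estimated correlation). The macrophage genes marco (4.53) and mafbb (3.37) and the myeloid regulator gene spi1b (3.50) rose, while rag2 (-5.50), a recombinase gene of lymphocytes, and cebp1 (-3.66) fell. Of 15 mesenchymal and fibroblast genes 8 rose and 0 fell, over the list alone too, among them the intermediate filament gene vim (6.29), anxa5b (5.17) and the cadherin gene cdh11 (4.25) (median 2.02, adjusted p = 0.00127, and adjusted p = 0.161 with an estimated correlation).

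Proliferation genes were lower in MPNST, with 22 of 76 down and 3 up (adjusted over the list alone 24 and 3) and a median of -1.65 (adjusted p = 0.00284, and adjusted p = 0.739 with an estimated correlation). The replication genes mcm6 (-4.56) and mcm7 (-1.63) and the centriole kinase gene plk4 (-3.51) fell, while the cyclin gene ccnd1 (4.22), kif20a (5.32) and birc5b (6.83) rose. This list too varied with the markers of other tissues, at 6.14 in rp replicate 3 and 9.76 to 9.81 in the seminomas. Of 15 nervous system genes 6 fell and 0 rose, over the list alone too, among them sncb (-7.38) and the synaptic vesicle genes sypb (-6.05) and sypa (-5.42) (median -1.03, adjusted p = 0.0428, and adjusted p = 0.407 with an estimated correlation).

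**Figure D3:**
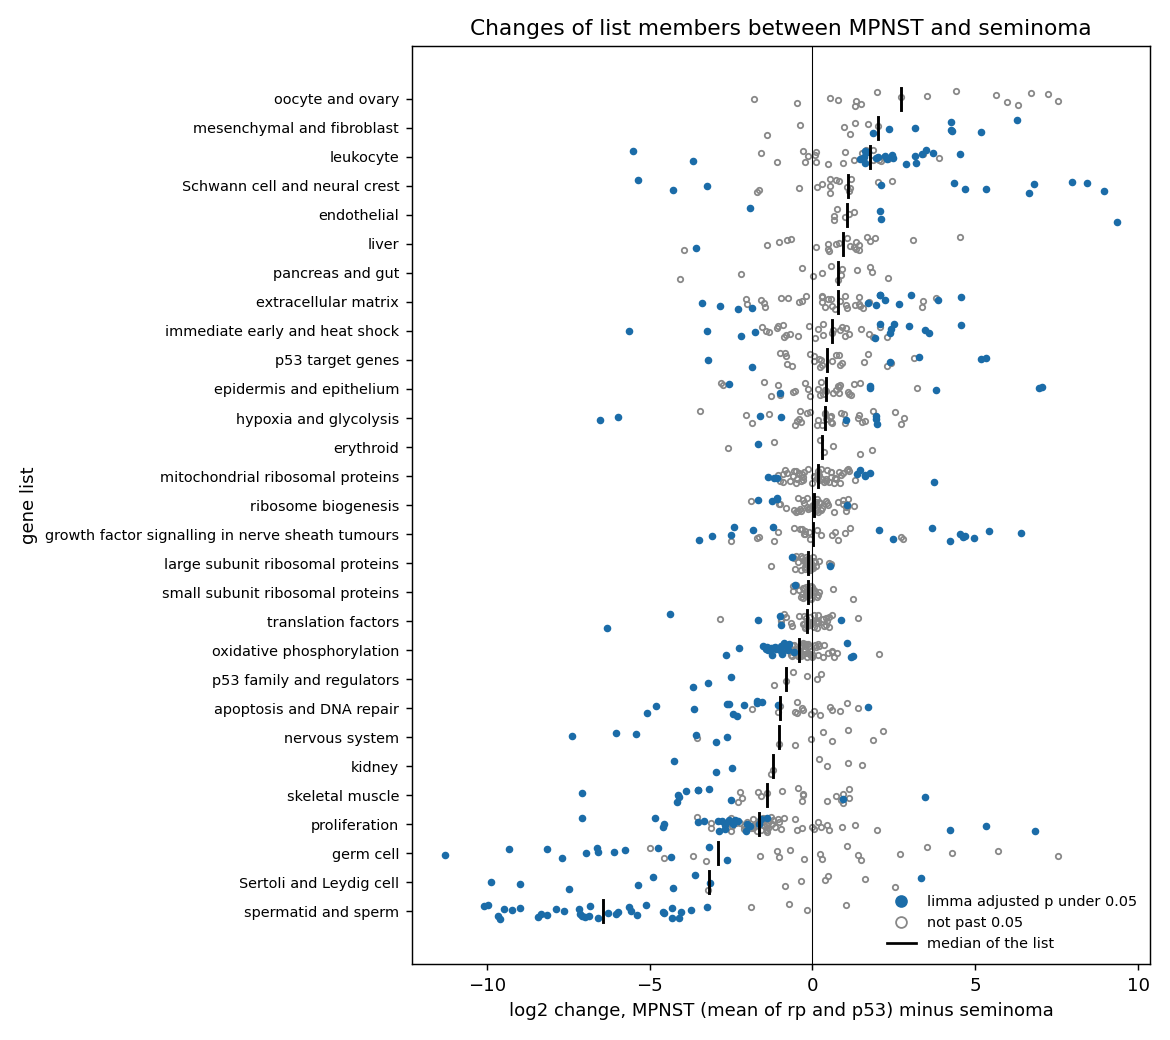
Log2 change between MPNST and seminoma (horizontal axis) of the tested genes of each list (vertical axis), blue where the adjusted p was under 0.05, with a line at each list's median. Spermatid and sperm genes lie farthest down with a median of -6.43, and mesenchymal genes have a median of 2.02.

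The p53 target list was not called against seminoma (adjusted p = 0.0737), with 4 of 28 genes up and 2 down, over the list alone too. The stress kinase gene plk3 (5.32 ± 0.49, adjusted p = 1.4e-05), phlda3 (5.19 ± 0.90, adjusted p = 0.00157), the apoptosis gene pmaip1 (3.26) and gadd45ba (2.37) rose. The p53 inhibitor gene mdm2 was at 6.76 ± 0.59 in MPNST and 9.93 ± 0.18 in seminoma (SD, n = 9 and 2), a fall of 3.22 ± 0.47 (adjusted p = 0.000519), and the apoptosome gene apaf1 fell by 1.84 ± 0.48 (adjusted p = 0.0156). Without either seminoma the call of apaf1 ended, with adjusted p-values of 0.171 without seminoma 1 and 0.0819 without seminoma 2, and so it did with the array sets as a block (0.0801) and within a set (0.0736), in a range of 7.37e-05 to 0.171. Of 9 p53 family members and regulators 3 fell, chek1 (-3.66), tp53bp1 (-2.49) and mdm2 (adjusted p = 0.179). The call of tp53bp1 did not stand under every alternative. The call of chek1 ended without seminoma 1 (0.0562), without seminoma 2 (0.0626) and at the threshold with the block (0.05), in a range of 2.07e-06 to 0.0626. In the apoptosis and DNA repair list 12 of 29 fell and 1 rose, over the list alone too, among them bida (-5.08), the mismatch repair gene msh6 (-4.81) and the helicase gene ercc3 (-3.62) (adjusted p = 0.084).

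Growth factor signalling genes of nerve sheath tumours had 10 of 38 up and 6 down (adjusted over the list alone 10 and 7, adjusted p = 0.17). The receptor gene met (6.42 ± 0.70), the ERK phosphatase gene dusp6 (4.97 ± 0.42) and the ETS factor gene etv5b (4.67 ± 0.71) rose and the ligand gene fgf8a (-2.50) fell. For the next 5 lists the counts adjusted over the list alone were the same except where given. Of 44 extracellular matrix genes 9 rose, such as mmp14b (3.84), and 4 fell, such as lama5 (-3.39) and col2a1a (-2.83) (adjusted p = 0.0896). Of 36 epidermis and epithelium genes 5 rose, such as krt18b (6.95) and icn (3.81), and 2 fell (adjusted p = 0.0896). Of 10 endothelial genes 3 rose and 1 fell (adjusted p = 0.0545). Of 40 immediate early and heat shock genes 9 rose, such as fosl2 (3.57), and 4 fell, such as the chaperone gene hspa8b (-5.64) (adjusted p = 0.0641). Of 40 hypoxia and glycolysis genes 4 rose and 4 fell, and adjusted over the list alone 2 and 2, with the glycolytic enzyme gene gpib at -6.52 (adjusted p = 0.274). Oxidative phosphorylation had 20 of 75 down and 3 up (adjusted over the list alone 21 and 3), with the complex I genes ndufb2 (-2.27) and ndufs7 (-1.52) among the falls (adjusted p = 0.0832). Of 29 skeletal muscle genes 9 fell, with neb (-7.08) and atp2a1 (-4.15), and 2 rose, over the list alone too (adjusted p = 0.0661).

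Few cytosolic ribosomal protein genes passed between the tumour types. Of 44 large subunit genes 1 rose, rpl22 (0.53 ± 0.17), and 1 fell, rplp0 (-0.62 ± 0.19) (adjusted p = 0.731). Of 30 small subunit genes 1 fell, rpsa (-0.54 ± 0.16) (adjusted p = 0.705), and adjusted over the list alone 0 of either list passed. Median centring ended these 3 calls, with adjusted p-values of 0.0625, 0.183 and 0.163. So did leaving out seminoma 1 (0.216, 0.158 and 0.173) or seminoma 2 (0.263, 0.236 and 0.22), for rpl22, rplp0 and rpsa in that order. The calls of rpl22 also ended without rp replicates 2, 4 and 6 and without p53 replicates 1, 2 and 3 (0.0525, 0.0635, 0.0627, 0.0772, 0.0596 and 0.0625), and that of rplp0 without p53 replicate 2 (0.054). With the array sets as a block rpl22 was at 0.194 and rpsa at 0.14, and within the set at 0.282 and 0.0529. Over all alternatives the adjusted p ran from 0.000309 to 0.282 for rpl22, 5.93e-05 to 0.236 for rplp0 and 0.000435 to 0.22 for rpsa. Of the 2 mutated genes measured, rpl35 was at -0.44 (adjusted p = 0.267, and 0.0454 without rp replicate 2) and rpl14 at 0.03 (adjusted p = 0.948), whose sign turned in several settings.

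Mitochondrial ribosomal proteins had 6 of 58 up and 3 down (adjusted over the list alone 3 and 2), with mrpl2 at 3.72 and mrpl41 at -1.37 (adjusted p = 0.125). Ribosome biogenesis had 1 of 45 up, nop58 (1.08), and 4 down, among them the RNA polymerase I factor gene ubtf (-1.69), and 0 passed over the list alone (adjusted p = 0.606). Translation factors had 1 of 45 up and 5 down (adjusted over the list alone 0 and 3), with eef1a1b at -6.30 and the poly(A)-binding protein gene pabpc1b at -4.36 (adjusted p = 0.844). With the array sets as a block the calls of nop58 (0.151) and pabpc1b (0.104) ended, as they did without seminoma 1 (0.218 and 0.101) and seminoma 2 (0.0834 and 0.0877), in ranges of 0.00139 to 0.218 and 2.7e-05 to 0.104. The call of ubtf ended without seminoma 1 (0.172) and 2 (0.0665), in a range of 2.99e-05 to 0.172. Of the other tissue lists, kidney had 3 of 9 down, such as slc5a12 (-4.24) (adjusted p = 0.154), liver 1 of 24 down, ass1 (-3.56) (adjusted p = 0.339), and erythroid 1 of 8 down, nt5c2l1 (-1.68) (adjusted p = 0.855), all over the list alone too. Pancreas and gut had 0 of 13 past the test in limma and 0 at an unadjusted p under 0.05 (adjusted p = 0.406). Of the 17 oocyte and ovary genes 0 passed and 3 had an unadjusted p under 0.05 (adjusted p = 0.0641), with h1m at 7.54 ± 3.10 and zp3a.1 at 7.23 ± 3.12. Without rp replicate 1 or p53 replicate 1, both low in oocyte transcripts, h1m passed with an adjusted p of 0.0289 and 0.0299, and zp3a.1 with 0.0327 and 0.0383. Both genes also passed with the array sets as a block and within the set of the seminomas. In that set the oocyte list averaged 11.02 to 11.91 log2 units on the rpL14, rpS5 and rpS11 arrays and 4.96 to 5.27 in the seminomas. Over all alternatives h1m ranged from 0.000119 to 0.338 and zp3a.1 from 7.02e-05 to 0.364. Median and mean differed in sign for ribosome biogenesis (0.0379 and -0.0142, test leaning up) and erythroid genes (0.297 and -0.116, test leaning up).

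In total 3388 probe sets passed between MPNST and seminoma, 1277 higher and 2111 lower in MPNST, and 3296 of them changed at least 2-fold. Without seminoma 1 the count was 1582 and without seminoma 2 it was 1697, each against a single seminoma assumed to vary like the other groups. With the array sets as a block 2732 passed, 1053 higher and 1679 lower. The block is estimated from the rp arrays alone, since the p53 arrays and the seminomas each lie in a single set. Within the set that holds both seminomas and the rpL14, rpS5 and rpS11 arrays, 2842 passed, 1038 higher and 1804 lower. The proliferation list lost its call with the block (adjusted p = 0.221) and within the set (0.209). So did germ cell genes (0.255 and 0.243), whose call also ended without p53 replicate 1 (0.0512). Within the set both shifts were smaller than the mean changes over all arrays, -1.49 and -2.38. On its rpL14, rpS5 and rpS11 arrays proliferation genes averaged 8.87 to 9.30 log2 units, against 9.76 to 9.81 in the seminomas. Germ cell genes averaged 8.06 to 8.63, against 8.99 to 9.09. The nervous system list lost its call without rp replicate 1 (0.0536), rp replicate 3 (0.0718) or p53 replicate 2 (0.0505), with the oocyte covariate (0.0797), without a filter (0.554) and with the stricter filter (0.773), and so did Sertoli and Leydig genes with those filters (0.126 and 0.431). Over all alternatives the adjusted p of these 4 lists ran from 1.45e-05 to 0.739, 2.3e-07 to 0.739, 0.0108 to 0.773 and 0.00284 to 0.431. Among 107 named genes that passed, all kept their direction and 80 also their call under every alternative in which they were tested, which for dim genes such as hormad1 excludes the stricter filter, while 22 lost it without seminoma 1 and 23 without seminoma 2, such as cdh11 without seminoma 1 (0.113, range 1.62e-05 to 0.113) and vim without seminoma 2 (0.0634, range 6.38e-05 to 0.0634).

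Each MPNST genotype was also set against the same 2 seminomas. Over all genes 2882 probe sets passed in rp tumours, 962 higher and 1920 lower, and 3252 in p53 tumours, 1314 higher and 1938 lower. Spermatid and sperm genes fell in rp tumours in 33 of 38 cases, and adjusted over the list alone in 34 (adjusted p = 5.94e-29, and adjusted p = 0.0424 with an estimated correlation). In p53 tumours 34 fell, and adjusted over the list alone 34 fell and 1 rose (adjusted p = 9.63e-26, and adjusted p = 0.0607 with an estimated correlation). Leukocyte genes had 10 up and 2 down in rp tumours, and adjusted over the list alone 11 and 2 (adjusted p = 0.000148, and adjusted p = 0.54 with an estimated correlation). They had 20 up and 2 down in p53 tumours, and adjusted over the list alone 24 and 2 (adjusted p = 4.57e-06, and adjusted p = 0.392 with an estimated correlation). Whether these changes differ between the genotypes was tested in the direct comparison of rp with p53.

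In rp tumours 10 lists were called, with counts below also adjusted over the list alone. Schwann cell and neural crest genes had 9 up and 4 down (list alone 9 and 4, adjusted p = 0.0234, and adjusted p = 0.306 with an estimated correlation). Mesenchymal genes had 7 up (list alone 7, adjusted p = 0.00217, and adjusted p = 0.152 with an estimated correlation). Proliferation had 19 down and 3 up (list alone 20 and 4, adjusted p = 0.0162, and adjusted p = 0.736 with an estimated correlation). Oxidative phosphorylation had 23 down and 2 up (list alone 24 and 3, adjusted p = 0.0314, and adjusted p = 0.733 with an estimated correlation). The oocyte list was higher with 0 genes past the test and 4 at an unadjusted p under 0.05 (adjusted p = 0.0234, and adjusted p = 0.733 with an estimated correlation). Sertoli and Leydig genes had 9 down and 1 up (list alone 9 and 1), nervous system genes 6 down (list alone 6) and germ cell genes 11 down (list alone 12). Their adjusted p-values were 0.0171, 0.0249 and 0.0314, and with an estimated correlation adjusted p = 0.152, 0.332 and 0.733.

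In p53 tumours 12 lists were called. Schwann cell and neural crest genes had 9 up and 3 down (list alone 10 and 3, adjusted p = 0.0216, and adjusted p = 0.272 with an estimated correlation). Immediate early and heat shock genes had 9 up and 3 down (list alone 11 and 3, adjusted p = 0.0145, and adjusted p = 0.392 with an estimated correlation). Extracellular matrix genes had 9 up and 4 down (list alone 9 and 4, adjusted p = 0.0432, and adjusted p = 0.392 with an estimated correlation). Proliferation had 20 down and 2 up (list alone 21 and 3, adjusted p = 0.00156, and adjusted p = 0.679 with an estimated correlation). Mesenchymal genes had 7 up (list alone 10 up and 1 down), germ cell genes 12 down (list alone 13) and Sertoli and Leydig genes 7 down (list alone 8 down and 1 up). Endothelial genes had 3 up and 1 down (list alone 4 and 1), skeletal muscle genes 9 down and 1 up (list alone 9 and 1) and nervous system genes 6 down (list alone 6). The adjusted p-values of these 6 lists were 0.0015, 0.0145, 0.0145, 0.0216, 0.0235 and 0.0414. With an estimated correlation they were adjusted p = 0.156, 0.679, 0.156, 0.392, 0.535 and 0.392. Without seminoma 1 the counts of probe sets were 1317 in rp and 1626 in p53 tumours, and without seminoma 2 they were 1437 and 1727. With the array sets as a block 2247 passed in p53 tumours, and the within-set value for rp tumours was 2842. No p53 array shares a set with a seminoma. The block for p53 tumours thus rests on the rpL35 arrays against the other rp arrays, where array set and mutant line coincide. It cannot show that the p53 count is free of array set.

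Within the rp group, the arrays labelled rpL35 were compared with the rpL14, rpS5 and rpS11 arrays, to see whether tumours of 1 mutant line differ from those of others. The antigen presentation gene mhc2daa was at 9.46 ± 0.61 on the arrays labelled rpL35 and at 2.38 ± 0.05 on the others (SD, n = 3 and 3), a change of 7.08 ± 0.40 (adjusted p = 0.000121). The p53 arrays, of the same array set, held it at 8.76 or higher too, so it did not follow the rpL35 label alone. Its call stood under every alternative run. Named falls were phactr4b (-3.04 ± 0.39), the mitochondrial coactivator gene ppargc1b (-2.59 ± 0.33), the Wnt effector gene tcf7l2 (-1.79 ± 0.19), the amyloid precursor gene appa (-1.66 ± 0.24) and rapgef1b (-1.51 ± 0.22), with adjusted p-values from 0.0218 to 0.0491. These 5 calls ended without rp replicate 6, with array weights and after median centring, which moved the median of all genes by 0.263 log2 units. In total 16 probe sets passed, 3 higher and 13 lower. The count was 1240 without rp replicate 2 and 2 without rp replicate 6. Without replicate 2 the arrays labelled rpL35 had oocyte means of 2.94 and 5.55, against 11.02 to 11.91 on the others. Those 1240 calls therefore cannot be told from a difference in oocyte transcripts. The 2 rp groups coincide with the array sets, so no within-set value can be had. For genes other than mhc2daa the p53 arrays, of the same set as those labelled rpL35, were not compared. For them the array set and the mutant line were therefore not told apart.

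Of the lists 7 were called between these rp groups, and 0 with an estimated correlation, where each had adjusted p = 0.795. In limma 0 of their genes passed, and the members with an unadjusted p under 0.05 numbered 15 in proliferation, 5 in spermatid, 4 in translation, 3 in germ cell, 2 in oocyte, 1 in pancreas and 0 in liver. Proliferation genes (adjusted p = 1.03e-05), oocyte and ovary genes and germ cell genes (both adjusted p = 4.26e-05) were lower on the arrays labelled rpL35. Of these arrays 2, replicates 1 and 3, had the lowest oocyte means of the rp group. With both the oocyte and liver covariates the mean change of germ cell genes went from -2.74 to 0.0445 (adjusted p = 0.996, range over all alternatives 3.34e-07 to 0.996). In that fit 0 of the 7 lists kept their call, the oocyte and liver lists being covariates themselves. Liver genes (adjusted p = 3.85e-05) and pancreas and gut genes (adjusted p = 0.0119) were higher, with rp replicate 3 at 12.12 and 10.82 log2 units. Spermatid and translation factor genes were higher too (both adjusted p = 0.0119), with spermatid genes at list means of 3.50 to 3.86 log2 units on the rp arrays, near the floor that differs between the array sets. The spermatid call ended after quantile normalization (0.711), without a filter (0.0885), with the oocyte covariate (0.133), and without rp replicate 3 (0.0986) or 6 (0.0636). The translation call ended without a filter (0.455) and without rp replicate 1 (0.0955) or 3 (0.243), and with the oocyte covariate its mean change turned to -0.00125. With a mean above 6 log2 units the spermatid mean turned to -0.555. Over all alternatives the adjusted p ran from 0.0106 to 0.795 for spermatid and 1.54e-05 to 0.899 for translation genes. Without rp replicate 3 the adjusted p was 0.209 for proliferation and 0.13 for liver, 3 lists were called and the pancreas list changed sign. Over all alternatives these p-values ran from 2.59e-13 to 0.795 for proliferation and 2.06e-08 to 0.795 for liver. Adjusted over the list alone, 1 translation factor and 1 ribosome biogenesis gene were higher.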

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

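The tests of array sets, oocyte or liver tissue, sequence variants, oocyte transcripts, liver and pancreas transcripts and mhc2daa were chosen only after the result was seen, and those of other splits of the arrays and of the tp53 chromosome before it. Within the 6 rp arrays, a result was singled out when its highest or lowest array lay far from the others compared with the whole range. Chance gives this in about 1 in 20 groups. It held for 18 of 73 results, 11 of them in rp replicate 3.

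The liver and pancreas transcripts of rp replicate 3 form the clearest pattern. That array had a liver list mean of 12.12 (others 4.13 to 4.72), a pancreas mean of 10.82 (others 3.08 to 4.22) and a kidney mean of 5.80 (others 3.85 to 4.25). Liver and pancreas tissue in the sample may account for it, since 31 of 37 tested members of both lists lay over 2 log2 units above every other MPNST array, with the fibrinogen genes fgb and fgg at 14.81 and 14.80 and the trypsinogen gene prss1 at 13.69. Whether another tissue stood wholly in place of the tumour could not be decided. The 9 nerve sheath genes tested kept a median share of 0.501 of their log2 excess over seminoma. No liver, pancreas or gut array was measured, so the share that another tissue would keep is unknown. The median gene s100b was at 8.53 against a mean of 12.9 on the other MPNST arrays. Shares ran from -0.0452 for foxd3 to 1.56 for pmp22a, with 0.162 for snai1a and 0.17 for crestin. A mixed sample stays open, and no biological explanation was tested.

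The same array was low in tumour and growth genes. In rp replicate 3 the proliferation list was at 6.14 (others 8.73 to 9.30) and the Schwann cell and neural crest list at 5.82 (others 6.99 to 7.39). The array was also lowest for defbl1 at 11.72 (13.49 to 13.99), dlx5a at 6.65 (10.37 to 11.70), fhl3b at 7.60 (9.73 to 10.99), s100b at 8.53 (12.37 to 13.21), sox10 at 6.39 (10.41 to 12.54) and tuba8l3 at 7.92 (12.32 to 14.11).

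Single genes stood apart on other rp arrays. In replicate 1, lmna was high at 4.79 (others 3.43 to 3.91) and tuba7l at 4.27 (3.16 to 3.34). In replicate 2, rpl35 was low at 12.91 (13.91 to 14.15). In replicate 4, cimap1b was high at 4.69 (2.25 to 2.56) and hoxb7a low at 2.94 (4.22 to 4.91). In replicate 5, add1 was high at 11.37 (8.86 to 9.63), and in replicate 6 snu13a was low at 4.33 (7.22 to 7.96).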

How the results depend on the processing

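Alternatives chosen after seeing the data were the covariates, the array set block and the comparison within an array set; the others were fixed beforehand. All 107 named genes that passed between MPNST and seminoma kept their direction and 80 their call, and of 14 between rp and p53 all kept direction and 2 their call, each wherever tested, which leaves dim genes out of the stricter filter. Of the 8 lists of each of these comparisons, 8 and 7 kept their direction and 0 their call. For the arrays labelled rpL35 against the other rp arrays, 6 of 6 genes and 3 of 7 lists kept direction. Signal over the floor limits the folds of dim genes. Every other probe set of the mutated genes was not run, since each has 1 probe set, and leaving out 1 seminoma leaves a lone one, assumed to vary like the other groups. Except where fewer genes or arrays were used, the cause was not tested.

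With a mean above 6 log2 units, which tests fewer genes, 17 probe sets (11 higher, 6 lower) passed for rp against p53, 2119 for MPNST, 1735 for rp and 1936 for p53 against seminoma, and 3 for rpL35 against other rp. With array weights these were 2441, 7396, 6501, 7131 and 2. Centring left 2 for rpL35 against other rp (2 higher, 0 lower, against 3 and 13), after moving the median of all genes by 0.263. For rpL35 against other rp, no filter gave 2609 (2404 higher, 205 lower) with 11 lists, the oocyte covariate 6 with 4 lists, and both covariates 4 lists. No filter lets dim probe sets in, and their median was higher on each array labelled rpL35 than on every other rp array. The 2404 higher calls therefore cannot be told from this difference in the signal floor. For rp against p53, the 9 MPNST arrays alone gave 22, the arrays labelled rpL35 alone 17 with 5 lists, the other rp arrays alone 80, both covariates 103 with 5 lists, and the array set block 17 with 5 lists. Both covariates gave 5533 for MPNST against seminoma. With an estimated correlation 0 lists were called in these 3 comparisons. Quantile normalization moved the rpl35 difference to -0.61 (exact permutation p = 0.0238).

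Leaving out 1 array at a time, the probe sets ranged from 10 to 93 and the lists from 2 to 11 for rp against p53, 1582 to 4038 and 7 to 10 for MPNST against seminoma, 1317 to 3508 for rp and 1626 to 3082 for p53 against seminoma, and 2 to 1240 and 3 to 10 for rpL35 against other rp. The rpl35 difference ranged from -0.652 to -0.067, that of rpl14 from -0.98 to -0.88 and that of array similarity from -0.039 to 0.0232, with 0.0228 without rp replicate 3 and 0.00231 without p53 replicate 2.

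Other values reversed. Between rp and p53, ccng1 was at -0.0115 with centring, -0.0057 with the oocyte covariate, and -0.0308, -0.0173 and -0.0711 without rp replicate 2, rp replicate 4 and p53 replicate 1 (range with 1 array left out -0.0711 to 0.144). There mdm2 was at -0.249 and rpl14 at 0.00955 both with the rpL35 arrays alone and with the block, and rpl35 at 0.0108 with the other rp arrays alone. The mean change of the proliferation list was -0.212 with the rpL35 arrays alone and with the block, against 0.413. Between MPNST and seminoma, rpl14 was at -0.096 with array weights, -0.0205, -0.0224 and -0.00662 without rp replicate 1, rp replicate 3 and seminoma 2 (range -0.0224 to 0.102), -0.0145 with MPNSTs as 1 group, -0.373 with the block and -0.369 within the set. Between the rpL35 and other rp arrays, mean log2 changes of lists were -0.555 for spermatid genes with a mean above 6, -0.00125 for translation genes with the oocyte covariate, -0.0257, 0.0445 and -0.75 for translation, germ cell and pancreas genes with both covariates, and -0.407 for pancreas without rp replicate 3 (range -0.407 to 3.46). Counted once per gene and setting, named genes fell short of the threshold 55 times with 1 array left out between MPNST and seminoma, 58 times between rp and p53 and 17 times within rp, and 42, 35 and 23 times in other settings.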

Other observations

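The tests of array sets, oocyte or liver tissue, sequence variants, oocyte transcripts and mhc2daa were chosen only after the result was seen, and those of other splits of the arrays and of the tp53 chromosome before it. Oocyte transcripts were abundant in several MPNSTs of both genotypes. The egg coat gene zp3a.1 was at 12.72, 12.42, 12.98 and 12.18 log2 units in rp replicates 2, 4, 5 and 6 and at 12.25 in p53 replicate 2. It was at 2.08 in rp replicate 1 and 1.78 in p53 replicate 1. The oocyte linker histone gene h1m was at 13.27, 12.92, 13.37 and 12.78 in rp replicates 2, 4, 5 and 6, and at 11.80 in p53 replicate 3. The translation regulator genes btg4 and zar1, the germ plasm organiser gene buc and the egg growth factor gene bmp15 followed the same arrays. Intermediate values occurred too, with zp3a.1 at 6.88 in rp replicate 3 and 9.99 in p53 replicate 3.

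A candidate explanation of this pattern is ovarian tissue in the samples, since 17 of 17 oocyte and ovary genes correlated above 0.8 with the mean of the others over the 9 MPNST arrays (lowest 0.841, median 0.991, across arrays that part into low and high). A difference in signal floor between arrays is argued against, because the list mean ranged 23.8 times as far as the median of the dim probe sets (9.03 against 0.379 log2 units). The rp or p53 genotype is argued against as the whole cause, because the range within p53 arrays was 0.911 of that within rp arrays. The difference between genotypes, 1.53 log2 units, had an exact two-sided permutation p of 0.512. Expression of oocyte genes by tumour cells was not tested and stays open.

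The 39 probe sets between rp and p53 MPNST were weighed against several explanations. Chance was not excluded, since the highest of the other splits of the 9 MPNST arrays called 1133 probe sets and 5 of 84 splits, the real one included, called at least 39. That highest split sets rp replicates 1 and 3 and p53 replicate 1, all low in oocyte transcripts, against the rest, which points to a structure of the samples, and the split by array set also called 39, with 17 called for the real groups once array set was a block. A difference between the array sets as sole cause is argued against by the 14 also called with the block and the other 25. These 25 lay at least 4.65 SE from 0 there, with a median share of 0.925 of their change. Choosing genes apart on every array favours such a share. With the oocyte and liver covariates 39 of 39 kept call and direction, which cannot decide on oocyte or liver tissue. The oocyte mean varied widely within both genotypes, and liver genes were high in rp replicate 3 alone. Probe sets that followed these tissues would hardly have been called between the genotypes. Other tissues were not used as covariates. Sequence variants under the probes may account for part. Of 14 other probe sets of the same genes 5 followed by at least 0.5 of the change and 3 went the other way. Linkage to tp53 is argued against for the 25 called genes with a symbol. Of these 0 lay on its chromosome, against 5.71% of the other tested genes (one-sided Fisher exact p = 1). Called probe sets without a symbol, the one with the smallest p among them, could not be placed. The seminomas lay nearer to the rp than to the p53 arrays for 34 of the 39 probe sets, and 23 changed by over 3 log2 units. A genotype effect stays open. Other differences between the fish of the rp and p53 groups were not tested and cannot be told from it here.

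For the lists between rp and p53 chance was not excluded either, with 8 lists called by the real split, 17 by the highest other and as many as the real one by 54 of 84 splits. The array set split called 9. For the arrays labelled rpL35 against the other rp arrays, the 10 splits are too few for a share under 0.05, with 16 probe sets in the real split and 4 in the highest other. In the same 10 splits, 1 gave as many probe sets and 9 as many lists, with 7 lists in the real split and 15 in the highest other.

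The antigen presentation gene mhc2daa was high or low by array set in MPNST, at least at 8.76 on the MPNST arrays of the set with the higher floor and at most at 2.44 on the others, and a second probe set, without a symbol, likewise with bounds of 11.14 and 3.96. The seminomas, of the set with the lower floor, were low as well, at 2.57 and 2.35 for mhc2daa and at 3.27 and 3.32 for the second probe set. The array set split parted 2 probe sets by over 3 log2 units, 7 of 84 splits parted as many and the highest parted 140. This count does not decide on the array sets. The gaps were 6.32 and 7.18 log2 units, against a range of 0.379 in the median of the dim probe sets, which argues against the floor alone. Another difference between the array sets and one between the fish of those sets cannot be told apart, since the sets hold different tumours.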
